A study of Rattus norvegicus with 18 samples.

How the data were processed

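Liver RNA from 18 male Wistar rats was measured on Affymetrix Rat Genome 230 2.0 arrays, 1 array per animal. Per the labels, the animals were fed from weaning on a semi-synthetic diet with a fat content of 4% by weight, in which the fat was virgin olive oil, sunflower oil or fish oil, and were killed at 6 or 24 months. The 3 oils and 2 ages gave 6 groups of 3 arrays. Per the labels' protocols, food was unrestricted for the first 2 months and rationed afterwards, and rats were housed with 3 animals to a cage. The labels do not say which animals shared a cage, so a cage and a group may coincide. P-values rest on the spread between animals within groups as housed. In the main fit this spread was pooled over all 6 groups. A group that varied more than the others, such as fish oil at 24 months, was thus judged by the pooled spread and not by its own. Liver pieces were kept in RNAlater, RNA was extracted with RNeasy columns, and biotinylated cRNA was made with the Affymetrix in vitro transcription kit, per the labels' protocols.

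The values used were the authors' deposited intensity values, 1 per probe set and array. The submitters' processing notes name RMA and Partek, without versions, and the order and settings of the steps were not given in the sources used here. RMA gives log2 values with a shared distribution, which these values do not have, so the notes and the values differ and the tool that made them is not given in the sources used here. The deposited intensities were linear, ran from 0.0 to 14085.0 and had a 2% trimmed mean between 99.17 and 99.39 on every array, so the arrays had been scaled to a common mean before deposit. A log scale had been planned for, so log2(signal + 16) was taken, and every fold change here is on that scale, which understates the change of dim genes. Of all values, 47.3% lay under the pseudocount of 16. Array medians ran from 15.5 to 18.4 at 6 months and from 18.5 to 20.6 at 24 months. For arrays, precision is limited by the number of animals, 3 in each group. No pair of arrays held identical values, and no array was left out of the main results.

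The table held 31042 probe sets. In the platform annotation, 20826 carried 1 gene symbol, 436 carried several and 9780 carried none. Of those with 1 symbol, 20758 were matched in the RefSeq gene table and 0 symbols needed updating. The probe set with the highest mean log2 signal stood for a gene, which gave 14217 genes, 4525 of them with more than 1 probe set. Probe sets with several symbols or none entered only an alternative over all probe sets. The table held 0 control probe sets with the AFFX prefix, so a planned check of RNA quality from their 3' to 5' ratio was not used here. Levels of erythroid, adipocyte, pancreas and hepatocyte markers were compared per array with exact two-sided permutation tests in place of it, 16 tests in all.

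Group means were fitted over all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 residual and 4.32 prior degrees of freedom). Contrasts gave the age effect in each oil and on average, the difference between each pair of oils at each age and on average, and a moderated F test of whether the age effect differed between oils. P-values were adjusted by Benjamini-Hochberg over the 14217 genes, with a threshold of 0.05. All adjusted p-values for genes are limma's unless another tool is named. Gene lists were tested with limma's camera (two-sided, preset inter-gene correlation of 0.01), adjusted over 32 lists within each comparison, and again with the correlation estimated from the data. The 32 lists, 21 of pathways and 11 of cell type markers, and a list of 30 core genes were fixed before the data were examined, as were the groups, the tests, the rule for naming genes and the alternatives not said to be added later. Of the core genes, 26 were measured. A list test speaks of genes, not of cells. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for preparation and figures.

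Genes were named by this rule. For each ageing comparison and each diet comparison averaged over ages, the 10 largest rises and 10 largest falls past the threshold were taken, and the 5 and 5 largest for diets at 1 age and the interaction. They had to have the same sign in each diet or age, or arrays that did not overlap between the groups compared, and predicted symbols were skipped. Up to 4 members of each list with the largest change past the threshold were added as examples, and the core genes were named whether called or not. Where fewer than 5 genes passed, the 5 with the smallest p were given as values. Acot1, the genes given for sample number 2 at 6 months, the genes given for the third fish oil liver at 24 months and genes called only under an alternative were chosen after their values were seen.

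The fitting code was tested on simulated data with 200 of 14217 genes changed. For ageing averaged over diets it recovered 67%, 89.5% and 92.5% of genes changed by 1.5, 2 and 4 fold, with 8, 10 and 13 false calls. For ageing in the sunflower oil group alone it recovered 0%, 58% and 81%, with 0, 5 and 6 false calls. For fish oil against virgin olive oil averaged over ages it recovered 35%, 84.5% and 87.5%, with 1, 9 and 10 false calls. For the interaction, 92.5% of 200 genes raised 4-fold in 1 diet were recovered, with 9 false calls. Here simulated log2 values were fitted directly, without the rounding and floor at 0 of the other cases, and sign was not checked. This share is thus not comparable with the others. In every case a gene had the same spread in all groups, with no pairing by number and no outlying liver. Of 500 unchanged random lists of 25 genes, 12 (2.4%) had a camera p under 0.05. Genes were drawn independently of each other in this simulation, so it could not show false calls from correlation within a list.

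Sample numbers 1 to 3 occur in every group although the animals differ. Deviations from the group means were correlated between arrays of the same number. At 6 months all 9 same-number pairs correlated above 0.1 (0.153 to 0.459, median 0.254), so the numbers paired the young arrays. At 24 months 2 of 9 did (median 0.031), and across ages 7 of 27 did. The pairing rests on the data, as the labels do not say what a number stands for. A replicate block over all arrays had been planned, and a replicate block within the 6-month arrays was added after the data were seen.

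Other alternatives, fixed before the data were examined, left out the dimmest 33.3% of genes, set trend and robust in eBayes, tested all probe sets, averaged the probe sets of a gene, quantile normalized the arrays again, used an ordinary linear model without moderation, fitted only the arrays of the groups compared, and left out each array in turn. Alternatives added after the data were seen were pseudocounts of 1 and 64, the fit without the number 2 arrays at 6 months, the list tests without the third fish oil array at 24 months, also with an estimated correlation, and splits of the arrays that part every same-number pair at 6 months.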

Results

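Liver transcripts were measured in 18 male rats kept for life on a diet whose fat was virgin olive oil (rich in monounsaturated oleic acid), sunflower oil (rich in n-6 polyunsaturated linoleic acid) or fish oil (rich in long-chain n-3 polyunsaturated fatty acids), and killed young, at 6 months, or old, at 24 months. The design asked how the liver transcriptome changes with age and with the type of dietary fat. Each of the 6 groups held 3 animals with 1 array each, and 14217 genes were tested. Unless stated otherwise, a change is a log2 fold change on the log2(signal + 16) scale, with the standard error of the limma fit, and signals are means of 3 arrays with their SD.

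Age separated the arrays before any test. The first principal component (22.2% of the variance) placed all 9 young livers below 0 and all 9 old livers above it. The second component (12.4%) separated the number 2 livers at 6 months, at -33.4 for olive oil, -26.3 for sunflower oil and -20.1 for fish oil, from the other young livers, at 3.5 to 21.6. The third fish oil liver at 24 months lay at 57.8 on the first component, against 13.5 and 23.7 for the other two livers of its group.

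**Figure D1:**
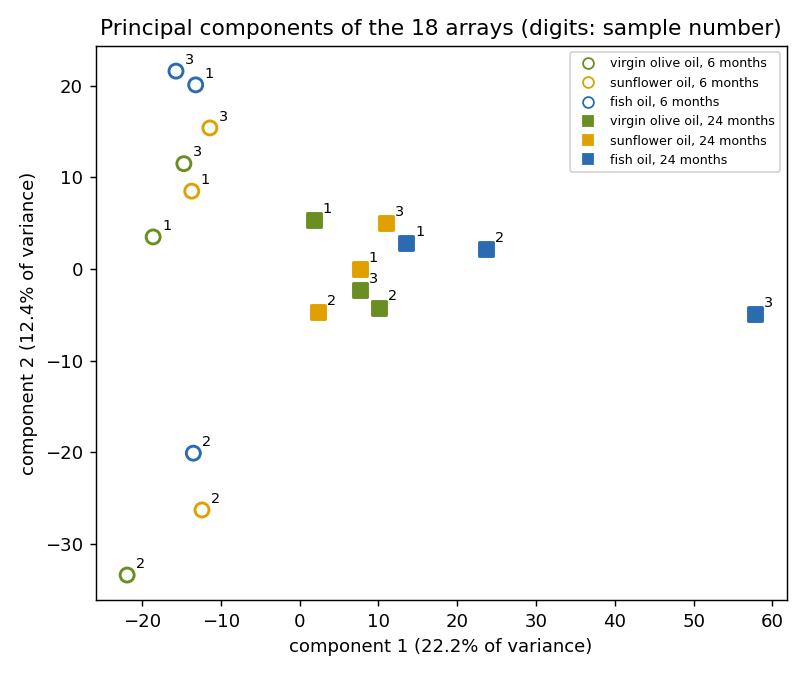
Positions of the 18 arrays on the first and second principal components of the log2 signals (component 1 with 22.2% and component 2 with 12.4% of the variance), coloured by oil, with open circles for 6 months, filled squares for 24 months and digits for the sample number. All 9 livers at 6 months lie below 0 on component 1, and the third fish oil liver at 24 months lies at 57.8.

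The comparison of old with young livers averaged over the 3 oils asked which genes change with age whatever the fat. A cohort, killing session or array batch that went with age could not be told apart from age here. The largest rises were in Akr1b7, an aldo-keto reductase (3.58 ± 0.537, 12.0-fold, adjusted p = 0.00194), Slc34a2, a sodium-dependent phosphate transporter (3.13 ± 0.237, 8.77-fold, adjusted p = 5.53e-06), Cyp4a8, a cytochrome P450 of the fatty acid hydroxylase family (3.08 ± 0.338, adjusted p = 0.00015), Vxn (2.88) and Mybl1, a transcription factor of the MYB family (2.55). The largest falls were in Sds, the serine dehydratase that feeds amino acid carbon into gluconeogenesis (-4.01 ± 0.63, 16.2-fold, adjusted p = 0.00256), and Inmt, the indolethylamine N-methyltransferase (-4.00 ± 0.386, adjusted p = 5.5e-05). Igfbp2, a binding protein of insulin-like growth factors, fell by 2.92 and Pfkfb1, the liver enzyme that sets fructose 2,6-bisphosphate, fell by 1.83. Inmt signal was 2315 ± 874 in young and 182 ± 216 in old olive oil livers, 1801 ± 499 and 130 ± 101 with sunflower oil, and 1222 ± 392 and 67.6 ± 52.1 with fish oil (SD, n = 3 each).

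Prss32 (2.36), Cd63 (-1.82), Eif4ebp3, a repressor of translation initiation (-1.73), Dhrs7l1 (-1.51) and Hao2, a peroxisomal hydroxyacid oxidase (-1.85, adjusted p = 0.0494), were also among the 10 largest changes in either direction. The call of Hao2 ended in 8 of 11 alternatives (adjusted p = 0.0297 to 0.164) and with 14 of 18 arrays left out in turn. In all, 734 genes passed the limma threshold, 394 higher and 340 lower with age, and 711 of them (96.9%) had the same sign in all 3 oils, which choosing genes by their average over the same oils favours. When the arrays were quantile normalized again, 698 genes passed, of which 282 were higher and 416 lower, so the balance between rises and falls turned over. Without the second olive oil liver at 24 months 489 genes passed.

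**Figure D2:**
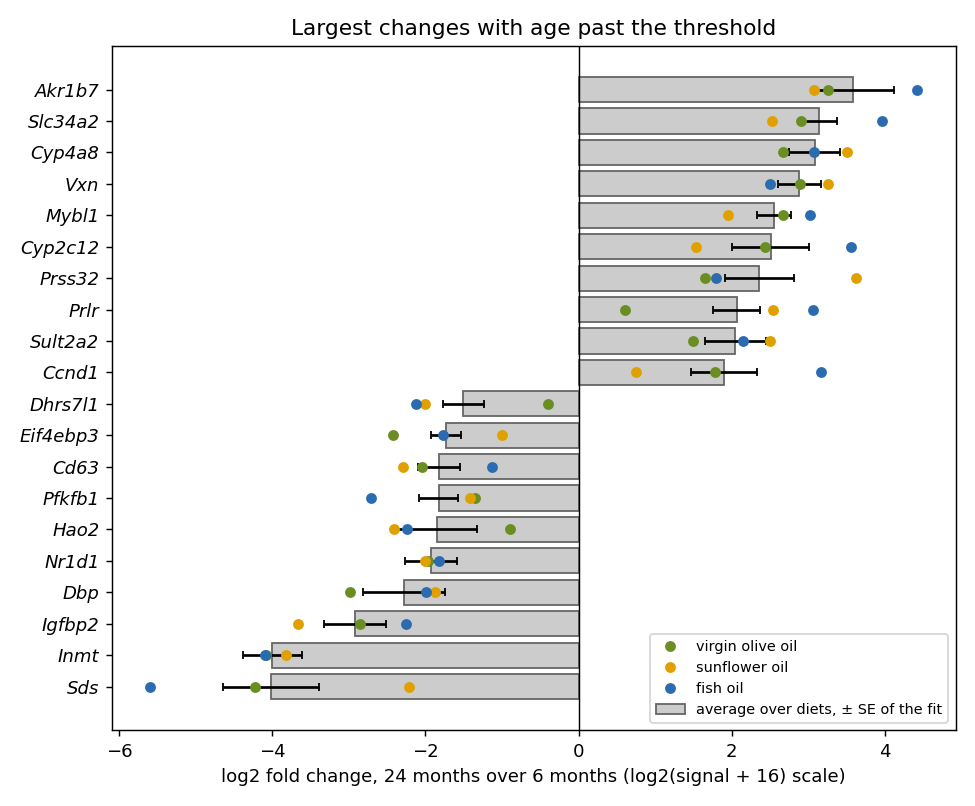
Log2 fold change of 24 months over 6 months for the 10 largest rises and 10 largest falls past the threshold, as grey bars averaged over oils with the standard error of the limma fit, and as points for each oil. Sds (-4.01) and Inmt (-4.00) fell the most and Akr1b7 (3.58) and Slc34a2 (3.13) rose the most on average.

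Genes of oxidative phosphorylation, the respiratory chain and ATP synthase, were lower in old livers. Of 57 measured members 17 fell and 0 rose (42 fell when adjusted over the list alone), among them Atp5me (-0.76), Ndufs3 (-0.54), Cyc1 (-0.52) and Ndufs7 (-0.50), and the list median was -0.29 (camera adjusted p = 5.04e-26; adjusted p = 0.165 with an estimated correlation). In gluconeogenesis and glycolysis, 4 of 18 members fell (4 when adjusted over the list alone), which were Pfkfb1, the transcriptional coactivator Ppargc1a (-0.94), the liver glycogen synthase Gys2 (-0.57) and the mitochondrial Pck2 (-0.54), with a median of -0.18 (adjusted p = 0.000157; 0.189 with an estimated correlation). Ppargc1a was also the 1 of 24 members that fell in mitochondrial biogenesis and dynamics (median -0.10, adjusted p = 0.00541; adjusted p = 0.107 with an estimated correlation). When quantile normalized again the oxidative phosphorylation median was -0.19 (adjusted p = 2.65e-10). Calls of Gys2 and Pck2 ended without the number 2 arrays at 6 months (adjusted p = 0.117 and 0.0939) and with 8 and 7 of 18 arrays left out in turn. The gluconeogenesis list did not pass without the number 2 arrays (median -0.05, adjusted p = 0.261).

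Among lipid genes, the desaturases that make polyunsaturated fatty acids fell while the list they belong to did not move as a whole. Fads1, the delta-5 desaturase (-1.45 ± 0.323, adjusted p = 0.0165), Fads2, the delta-6 desaturase (-1.15, adjusted p = 0.0353), and the elongase Elovl2 (-0.69) fell, 3 of the 22 members of fatty acid synthesis and desaturation (3 lower and 1 higher when adjusted over the list alone; median -0.10, camera adjusted p = 0.139; adjusted p = 0.631 with an estimated correlation). Cyp4a8, Pdk4, the kinase that holds back pyruvate oxidation (1.10), and the lipid droplet coat protein Plin2 (0.86) rose, 3 of 31 PPAR-alpha targets and fatty acid oxidation genes (3 when adjusted over the list alone; median 0.25, adjusted p = 0.0362; 0.624 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-1.44, adjusted p = 0.0468), and Cyp27a1 (-0.48) fell, 2 of 20 bile acid genes (4 lower and 1 higher when adjusted over the list alone; median -0.12, adjusted p = 0.0875; 0.477 with an estimated correlation). None of 19 cholesterol synthesis genes passed limma's threshold, over all genes or adjusted over the list alone, with a median of -0.23 (adjusted p = 0.00424; 0.486 with an estimated correlation). The fatty acid transporter Cd36 rose (1.54) and Apoa1 fell (-0.39) among 25 lipoprotein and lipid transport genes (1 higher and 2 lower when adjusted over the list alone; median -0.11, adjusted p = 0.0545; 0.405 with an estimated correlation). Without the number 2 arrays at 6 months the calls of Fads1, Fads2 and Cyp7a1 ended (adjusted p = 0.0773, 0.148 and 0.189), the median of fatty acid synthesis became 0.44 (adjusted p = 0.00296), and those of the cholesterol and PPAR-alpha lists turned to 0.04 (0.592) and -0.09 (0.201). Without the third fish oil liver at 24 months the calls of Fads2, Elovl2, Cyp7a1 and Apoa1 ended (adjusted p = 0.0672, 0.0756, 0.0684 and 0.064), and with each of the 18 arrays left out in turn they ended in 9, 13, 14 and 13 fits. Scd, the stearoyl-CoA desaturase, had a difference of 3.52 ± 1.45 (adjusted p = 0.171), with signals from 25.3 to 8930 among the young olive oil livers alone.

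Most interferon response genes rose with age. Of 25 measured members 18 rose and 0 fell (22 rose when adjusted over the list alone), including the chemokine Cxcl10 (1.67), the interferon-inducible GTPases Igtp (1.66) and Irgm (1.65) and the transcription factor Irf1 (1.45), with a median of 1.06 (camera adjusted p = 3.08e-17; adjusted p = 0.107 with an estimated correlation). In antigen presentation, RT1-CE5, a class I molecule (1.65), the peptide transporter Tap1 (0.94) and the immunoproteasome subunit Psmb8 (0.90) rose, 3 of 19 members (6 when adjusted over the list alone), with a median of 0.51 (adjusted p = 1.56e-05; 0.405 with an estimated correlation). Among the 5 probe sets of RT1-CE5, differences ran from 0.05 to 1.65. The lowest came from a probe set with a mean log2 signal of 4.12, near the floor that the pseudocount sets, but another at 6.5, close to the 6.57 of the one used, gave 0.54 (adjusted p = 0.158). Without the third fish oil liver at 24 months the antigen presentation median was 0.31 (adjusted p = 0.000105). Macrophage markers had a median of 0.38 with Cd68 (0.72) the 1 of 11 that rose (7 when adjusted over the list alone; adjusted p = 0.00217; 0.405 with an estimated correlation), and 10 monocyte and granulocyte markers had a median of 0.60 with 0 called over all genes and 7 when adjusted over the list alone (adjusted p = 0.00156; 0.405 with an estimated correlation). Calls of Cxcl10, Tap1 and Cd68 ended without the number 2 arrays (adjusted p = 0.0524, 0.0588 and 0.104). With each of the 18 arrays left out in turn, calls ended for Cd68 in 12 fits, Tap1 in 3 and Psmb8 in 1.

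Several cell cycle and p53 pathway genes were higher in old livers. Cyclin D1 (Ccnd1, 1.90), the replicative helicase subunit Mcm4 (0.53), the topoisomerase Top2a (0.52) and the mitotic kinase Cdk1 (0.42) rose, 4 of 29 cell cycle genes (11 when adjusted over the list alone), with a median of 0.25 (camera adjusted p = 4.48e-06; adjusted p = 0.0759 with an estimated correlation). The p53 targets Cdkn1a, an inhibitor of the cell cycle (1.33), Ccng1 (1.02) and Mdm2 (0.39) rose together with the chemokine Ccl2 (1.09), 4 of 25 DNA damage response, senescence and SASP genes (8 when adjusted over the list alone; median 0.28, adjusted p = 0.0177; 0.165 with an estimated correlation). Nfe2l2, which codes for the antioxidant regulator NRF2, rose (0.94 ± 0.111, adjusted p = 0.000274) while the mitochondrial enzymes Prdx5 (-0.59) and Txnrd2 (-0.53) fell, among 38 antioxidant and NRF2 target genes (2 higher and 4 lower when adjusted over the list alone) with a median of -0.08 (adjusted p = 0.0275; 0.405 with an estimated correlation). The antioxidant enzymes Sod2 (0.10), Cat (-0.06) and Gpx1 (0.03) did not pass, nor did Nqo1 (-0.67, adjusted p = 0.0873) and Hmox1 (0.66, adjusted p = 0.0698). Of 23 telomere genes Xrcc6, a DNA end-binding protein, fell (-0.54; 1 when adjusted over the list alone), with a list median of -0.04 (adjusted p = 0.246; 0.422 with an estimated correlation), and Tert (0.07) and Terf1 (0.18) did not pass. Without the number 2 arrays at 6 months the calls of Cdkn1a, Ccl2, Cdk1, Top2a and Xrcc6 ended (adjusted p = 0.0962, 0.0821, 0.132, 0.0561 and 0.0856). Those of Mdm2, Top2a and Cdk1 ended without the third fish oil liver at 24 months (adjusted p = 0.0598, 0.0604 and 0.0832). With each of the 18 arrays left out in turn, calls ended for Cdk1 in 14 fits, Ccl2 in 12, Mdm2 and Top2a in 10 each and Cdkn1a in 4. Top2a, Cdk1 and Ccl2 were dim, with mean log2 signals of 4.57, 4.39 and 4.89, near the floor that the pseudocount sets. The other probe set of Top2a gave 0.28 (limma adjusted p = 0.269 over all probe sets). Without the number 2 arrays the antioxidant list had an adjusted p of 0.0777 (0.138 without the third fish oil liver at 24 months, and 0.902 when quantile normalized again).

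Genes expressed more in female than in male rat liver were among the largest rises. Akr1b7, Cyp2c12, the female-specific cytochrome P450 of rat liver (2.51), the prolactin receptor Prlr (2.07) and the hydroxysteroid sulfotransferase Sult2a2 (2.05) rose, in a female-biased list where 5 of 15 members rose and 2, Hao2 and the small heat shock protein Hspb1, fell (6 and 2 when adjusted over the list alone; median 0.22, camera adjusted p = 0.0207; adjusted p = 0.324 with an estimated correlation). Of 18 male-biased genes Cyp2a2 fell (-0.85; 2 when adjusted over the list alone), with a median of -0.43 (adjusted p = 0.0022; 0.423 with an estimated correlation) that was -0.13 without the third fish oil liver at 24 months (adjusted p = 0.0107), and the male-specific Cyp2c11 did not pass (-0.41, adjusted p = 0.269). Of 18 clock genes 4 fell, among them the transcription factors Dbp (-2.28), Nr1d1 (-1.93) and Nr1d2 (-1.07), and 2 rose, among them Nfil3 (1.15), a repressor that binds the same sites as Dbp (5 higher and 7 lower when adjusted over the list alone; median -0.26, adjusted p = 0.285; 0.533 with an estimated correlation). A different hour of killing at the 2 ages was not tested as a cause of the clock gene changes. Hspb1 (-1.05) and Xbp1 (-0.66) fell among 27 unfolded protein and heat shock genes (3 higher and 3 lower when adjusted over the list alone; median -0.17, adjusted p = 0.0275; 0.422 with an estimated correlation). Xenobiotic metabolism genes had a median of -0.14 with 0 of 34 past limma's threshold, also when adjusted over the list alone (adjusted p = 0.00528; 0.405 with an estimated correlation; median -0.09 and 0.0437 without the third fish oil liver at 24 months). The female-biased list had an adjusted p of 0.287 and the unfolded protein list of 0.076 without the number 2 arrays, without which Dbp and Nr1d2 also lost their calls (adjusted p = 0.102 and 0.0634). When quantile normalized again the male-biased (0.267), xenobiotic (0.591) and unfolded protein (0.923) lists did not pass.

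Hepatocyte markers had a median of -0.17 (1 of 10 fell, Apoa1, and 2 when adjusted over the list alone; camera adjusted p = 0.00131; adjusted p = 0.241 with an estimated correlation; 0.353 when quantile normalized again). Single members of lists that did not pass camera were called. These were C6, a complement component (1.35), and A2m, a protease inhibitor (-1.05), in acute phase and complement (median 0.004, adjusted p = 0.908), Mmp14 (0.73) in extracellular matrix (-0.03, 0.829), Cd4 (0.55) among T and NK cell markers (0.16, 0.102), Xbp1 among B and plasma cell markers (-0.04, 0.323) and the elastase Cela1 (-1.37) among exocrine pancreas markers (-0.02, 0.246). Calls of A2m and Mmp14 ended without the number 2 arrays at 6 months (adjusted p = 0.0739 and 0.058), and that of Apoa1 ended without the third fish oil liver at 24 months (adjusted p = 0.064). The call of Cd4 (adjusted p = 0.0363) ended in 3 of 11 alternatives, and with each of the 18 arrays left out in turn calls ended for Apoa1 in 13 fits, Cd4 in 10 and Mmp14 in 3. Markers of stellate cells (median 0.06, adjusted p = 0.942), endothelium (0.01, 0.942), cholangiocytes (0.13, 0.536), erythroid cells (-0.04, 0.908) and adipocytes (0.11, 0.382) held no called member. For stellate and endothelial markers the camera direction was down although median and mean were above 0, and the mean of extracellular matrix genes (0.04) was above 0. As mean log2 levels per array, pancreas markers differed by -0.14 with age (exact permutation p = 0.0142, adjusted p = 0.125) and hepatocyte markers by -0.19 (exact p = 0.0156, adjusted p = 0.125), and none of the 16 tests of marker levels passed after adjustment.

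**Figure D3:**
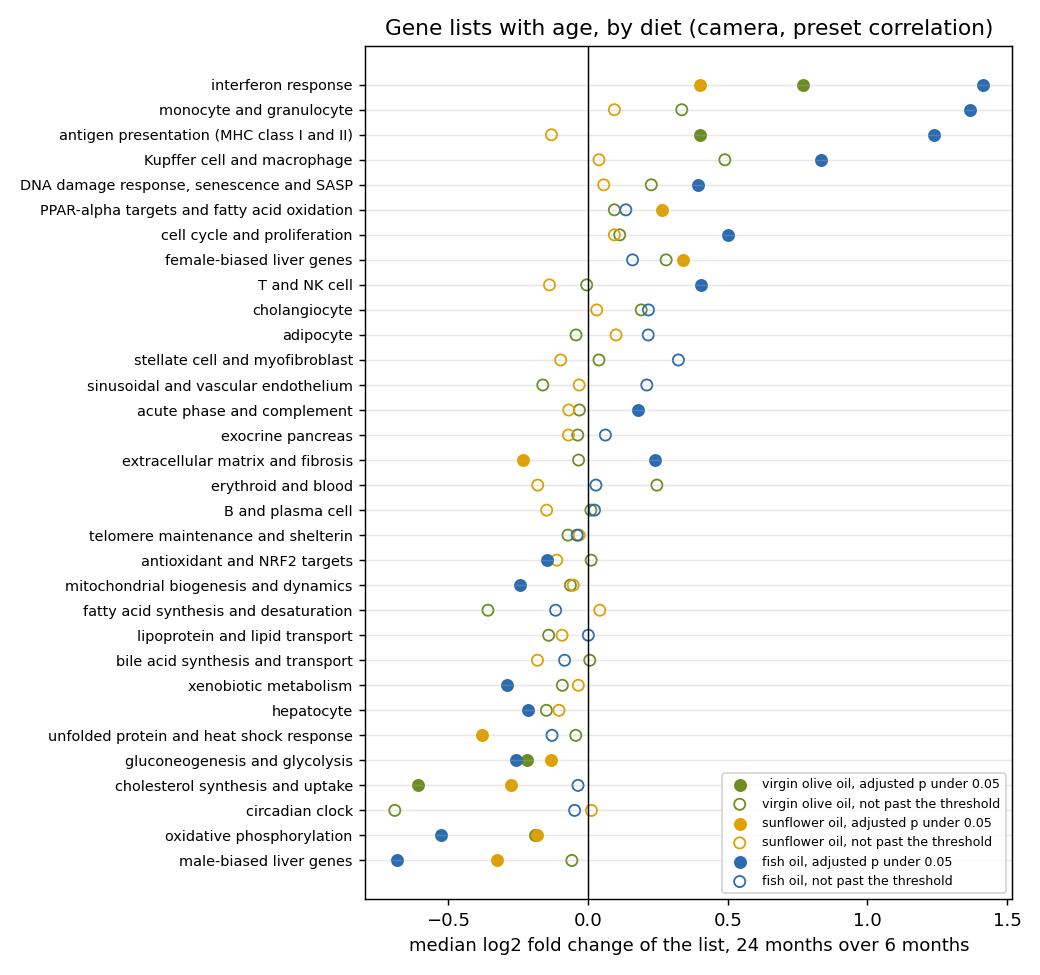
Median log2 fold change of 24 months over 6 months of each of the 32 gene lists, 1 point per oil, filled where camera with a preset correlation gave an adjusted p under 0.05. Interferon response lies highest, at 0.77 with olive oil, 0.40 with sunflower oil and 1.41 with fish oil, and oxidative phosphorylation lies at -0.19, -0.18 and -0.53.

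In rats fed virgin olive oil, old livers had more Slc34a2 (2.90), Vxn (2.89), Mybl1 (2.67), RT1-CE5 (2.49) and Phlda3, a p53 target (2.37 ± 0.306, adjusted p = 0.00968), and the interferon-induced Ifit2 (1.71) and Rtp4 (1.38). Olr59 (1.80), Popdc2 (1.66), Mal2 (1.16) and Nfe2l2 (1.02) also rose. Inmt (-4.08), Eif4ebp3 (-2.42), Nipal2 (-1.37), the phosphofructokinase Pfkm (-1.11), Hoga1 (-1.11) and the mitochondrial adenylate kinase Ak3 (-0.74) fell. Other probe sets of Ak3 and Hoga1, at mean log2 signals of 8.44 and 7.94, were compared for ageing averaged over oils only. There they gave -0.11 and -0.53 (limma adjusted p = 0.711 and 0.296 over all probe sets), against -0.38 and -0.97 for those used. Interferon response genes had a median of 0.77 with 1 of 25 called over all genes and 11 when adjusted over the list alone (camera adjusted p = 1.35e-13; adjusted p = 0.579 with an estimated correlation). Antigen presentation had a median of 0.40 (1 of 19 rose, 2 when adjusted over the list alone; adjusted p = 0.00561; 0.677 with an estimated correlation) and oxidative phosphorylation one of -0.19 (0 of 57, also over the list alone; adjusted p = 4.74e-08; 0.657 with an estimated correlation), which was -0.11 when quantile normalized again (adjusted p = 0.00832). Cholesterol synthesis (-0.61, adjusted p = 8.69e-05) and gluconeogenesis (-0.22, adjusted p = 0.00148) were also lower (0.657 for both with an estimated correlation; 0.231 and 0.36 without the number 2 arrays). Limma called 20 genes, 14 higher and 6 lower. The count was 39 with a replicate block within the paired 6-month arrays and 1, Tkfc, without the number 2 arrays. It was 3, 7, 3 and 8 without the first and second young and the second and the third old livers of the group. All 17 genes named as called here lost their calls without the number 2 arrays, and 0 of them held in all 12 alternatives.

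In rats fed sunflower oil, no gene passed. The smallest p-values belonged to Vxn (3.25, adjusted p = 0.0667), Slc34a2 (2.53), Cyp4a8 (3.50), Ptk7 (1.81) and Inmt (-3.82, adjusted p = 0.0787). Unfolded protein and heat shock genes had a median of -0.38 (camera adjusted p = 4.23e-05; adjusted p = 0.508 with an estimated correlation), oxidative phosphorylation genes of -0.18 (1.55e-07; 0.595 with an estimated correlation; median -0.08 and 0.0631 when quantile normalized again) and interferon response genes of 0.40 (0.000945; 0.595 with an estimated correlation). Female-biased genes had a median of 0.34 (adjusted p = 0.00557; 0.508 with an estimated correlation; 0.114 without the number 2 arrays). Antigen presentation had a median of -0.13 (adjusted p = 0.361; 0.851 with an estimated correlation). No member of these lists was called over all genes. Adjusted over the list alone, 4 female-biased genes rose and 2 fell, and 0 of the other lists named passed. Limma called 0 genes, with 1086 at an unadjusted p under 0.05, and an ordinary linear model called 0. With a replicate block within the paired 6-month arrays 17 genes passed, without the dimmest genes 17, without the first young liver 2 and without the first old liver 13.

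In rats fed fish oil, interferon response, antigen presentation and cell cycle lists were higher in old livers and the oxidative phosphorylation list was lower, with the preset correlation. Of these lists only cell cycle also passed with an estimated correlation. The largest rises were in Akr1b7 (4.42), Lcn2, an iron-sequestering acute phase protein (4.16), Slc34a2 (3.96 ± 0.411, adjusted p = 0.000536), Cyp2c12 (3.55), Cxcl10 (3.17), Ccnd1 (3.16), Cyp4a8 (3.07), Prlr (3.06), Gpnmb, a glycoprotein of macrophages (3.05), and Mybl1 (3.02). The largest falls were in Sds (-5.59), Inmt (-4.10), Pfkfb1 (-2.71), Dhrs7l1 (-2.12), the aquaglyceroporin Aqp3 (-1.84), Cela1 (-1.83), Eif4ebp3 (-1.77), Mmd2 (-1.65), Fuom (-1.45) and Tcea3 (-1.43). Aqp3 was dim over all arrays, with a mean log2 signal of 4.42. Limma called 243 genes, 176 higher and 67 lower (72.4% higher), against 101, 60 higher and 41 lower, when the arrays were quantile normalized again. Of the 243, 211 (86.8%) had the same sign with olive oil and 188 (77.4%) with sunflower oil, and 13 were called with olive oil as well. Young livers of the 3 oils went together by sample number, so these shares are not independent of each other.

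The third old liver of the fish oil group held far higher signals of several of these genes than the first and second. Lcn2 stood at 5520 against 75.5 and 489.5, Cyp2c12 at 5685 against 152.5 and 317, and Cxcl10 at 1204 against 48.1 and 150.9. Without it limma called 15 genes, 14 of them among the 243, and all 243 kept their sign. The count was also 7, 19 and 104 without the third, first and second young livers, and 36 and 562 without the second and first old ones. Of the 48 genes named as called in this group, 43 lost their calls without the third old liver. Slc34a2 and Mybl1 were the 2 of 48 named genes whose calls held in all 12 alternatives, and both held with each array left out.

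Interferon response, antigen presentation and immune cell marker lists were higher in old fish oil livers. Of 25 interferon genes 14 rose (19 when adjusted over the list alone), among them Cxcl10, Cxcl9 (2.98), Igtp (2.53) and Irgm (2.24), with a median of 1.41 (camera adjusted p = 1.77e-17; adjusted p = 0.0796 with an estimated correlation). Of 19 antigen presentation genes 5 rose (16 when adjusted over the list alone), among them the class II molecules RT1-Da (2.22) and RT1-Db1 (1.88), the invariant chain Cd74 (2.13) and Tap1 (1.85), with a median of 1.24 (8.39e-12; 0.136 with an estimated correlation). The monocyte and granulocyte markers Fcnb (2.04), Itgax (1.85) and Itgam (1.43), the T and NK cell markers Gzma (1.12), Cd8a (1.08) and Klrd1 (0.77) and the macrophage marker Cd68 (1.46) rose. Their lists had medians of 1.37 (3 of 10, and 8 when adjusted over the list alone; adjusted p = 1.44e-05), 0.41 (3 of 17, and 6; 3.53e-05) and 0.83 (1 of 11, and 8; 2.32e-05), with adjusted p = 0.2, 0.136 and 0.165 with an estimated correlation. In the third old liver the medians lay above the mean of the other two by 0.84 for interferon, 1.84 for antigen presentation, 1.6 for monocyte and granulocyte, 0.65 for T and NK cell and 0.72 for macrophage genes. Without it the medians of antigen presentation (0.59, adjusted p = 8.43e-10) and of monocyte and granulocyte genes (0.60, adjusted p = 0.000729) were lower and still passed. Of the single genes named in this paragraph, only Cxcl10 kept its limma call without that liver (adjusted p = 0.0304). The calls of all others ended, with adjusted p from 0.065 (Tap1 and Cxcl9) to 0.229 (Cd8a and Klrd1). Over all arrays Fcnb, Itgax, Itgam, Cd8a and Klrd1 were dim, with mean log2 signals of 4.46 to 4.82, near the floor that the pseudocount sets.

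In the fish oil group the cell cycle list was higher and the oxidative phosphorylation list lower in old livers, with most members not called. Ccnd1, the helicase subunits Mcm6 (1.39) and Mcm5 (0.97) and Top2a (1.14) were among 7 of 29 cell cycle genes that rose (11 when adjusted over the list alone), with a median of 0.50, a call that held with an estimated correlation (adjusted p = 1.41e-10 and 0.00839). This list lay 0.37 above the mean of the other two in the third old liver. Without that liver the calls of Ccnd1, Mcm6, Mcm5 and Top2a ended (adjusted p = 0.162, 0.144, 0.0852 and 0.132), and the list median was 0.42 (adjusted p = 2.74e-09; 0.00114 with an estimated correlation). Mcm6, Mcm5 and Top2a were dim over all arrays, with mean log2 signals of 4.93, 5.1 and 4.57. Of 57 oxidative phosphorylation genes 7 fell (47 when adjusted over the list alone), among them Atp5me (-1.16), Ndufs3 (-0.84), Cyc1 (-0.80) and Ndufs7 (-0.79), with a median of -0.53 (adjusted p = 4.99e-34; 0.0796 with an estimated correlation). Mean hepatocyte marker levels (log2) were lower as well, at 12.27 to 12.43 on the young and 11.9 to 12.19 on the old fish oil arrays. Whether the oxidative phosphorylation genes fell beyond these markers was not tested. Mitochondrial biogenesis genes had a median of -0.24, with 0 of 24 called over all genes and 2 lower and 1 higher adjusted over the list alone, and this list also held with an estimated correlation (adjusted p = 0.000413 and 0.0306). Without the third old liver its median was -0.15 (adjusted p = 0.00192), and it did not pass with an estimated correlation (0.0522). Nfe2l2 (1.12), Pdk4 (1.93), Ccl2 (2.41) and the stress-induced factor Atf3 (1.80) rose and Cyp27a1 (-0.72), Prdx5 (-0.84) and Txnrd2 (-0.69) fell. Male-biased genes had a median of -0.68 with 0 of 18 called, also over the list alone (adjusted p = 0.000565; 0.392 with an estimated correlation). Without the third old liver, where this list lay 1.55 below the mean of the other two, its median was -0.08 (adjusted p = 0.581).

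Whether the age effect differed between oils was asked directly. No gene passed, and the smallest p-values belonged to Cd7, Scn10a, Olr59, Kifc3 and Naaa, all with an adjusted p of 0.446. Limma's moderated F test called 0 genes, with 785 at an unadjusted p under 0.05, and the ordinary linear model called 0. Without the first fish oil liver at 24 months it called 5, C1h16orf54, Gpnmb, Kifc3, Mmp12 and Pla2g2d. Differences between pairs of oils gave 0 limma calls each, with 787, 971 and 544 at an unadjusted p under 0.05 for fish minus olive, fish minus sunflower and sunflower minus olive oil. The larger count of calls in the fish oil group was thus a count, and no single gene passed a test of the difference. Of the gene lists, the rise of cell cycle genes was larger with fish than with sunflower oil by 0.47 (median difference, camera adjusted p = 9.85e-08; 0.032 with an estimated correlation). The third fish oil liver at 24 months lay 0.37 above the other two in this list, and without it the difference was 0.37 (adjusted p = 4.46e-06; 0.00798 with an estimated correlation).

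The comparison of fish oil with virgin olive oil averaged over both ages asked what the fat alone changes. Hdc, the histidine decarboxylase that makes histamine, was higher with fish oil (2.72 ± 0.42, 6.59-fold, adjusted p = 0.0499). Apoa4, the apolipoprotein A-IV of triglyceride-rich lipoproteins, was lower (-0.85 ± 0.125, 1.80-fold, adjusted p = 0.0499). Hdc signal was 25.2 ± 23.2 with olive and 315 ± 245 with fish oil at 6 months, and 131 ± 98.9 and 836 ± 291 at 24 months (SD, n = 3). Apoa4 signal was 5845 ± 600 and 3279 ± 648 at 6 months, and 6192 ± 517 and 3465 ± 612 at 24 months. These were the 2 genes that limma called. An ordinary linear model called 0, and 826 genes had an unadjusted p under 0.05. Both lay at the threshold, so that the call of Hdc ended in 8 of 12 alternatives (adjusted p = 0.00236 to 0.287) and that of Apoa4 in 6 of 12 (0.013 to 0.212). Of the 12 arrays of these groups, only the first fish oil liver at 24 months left the count at 2 when removed, with Mmp12 (1.63, adjusted p = 0.00551) called in place of Hdc. Removal of the second fish oil liver at 6 months or the first olive oil liver at 24 months left 1 gene, and removal of any other array left 0.

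Prps2 (0.81, adjusted p = 0.124), Tpd52l1 (1.11) and Nudt7, a peroxisomal CoA hydrolase (0.87), had the next smallest p-values. Fatty acid synthesis and desaturation genes were lower with fish oil, with a median of -0.64 and 20 of 22 members negative (camera adjusted p = 2.72e-06; adjusted p = 0.445 with an estimated correlation), and so were cholesterol synthesis genes (-0.27, adjusted p = 0.00184; 0.577 with an estimated correlation). Adjusted over the list alone, 1 and 0 members fell. Fads1 stood at -1.69 (adjusted p = 0.422), Fads2 at -1.15 and their regulator Srebf1 at -1.09. PPAR-alpha targets were higher (0.26, adjusted p = 1.36e-05; 0.566 with an estimated correlation; 3 rose when adjusted over the list alone). Lipoprotein genes (-0.20, adjusted p = 1.17e-05; 4 fell when adjusted over the list alone) and hepatocyte markers (-0.17, adjusted p = 9.15e-07; 2 when adjusted over the list alone) were lower, both at 0.104 with an estimated correlation. When quantile normalized again their medians were -0.07 (adjusted p = 0.0351) and -0.05 (adjusted p = 0.0429). Cell cycle genes were higher (0.16, adjusted p = 3.6e-06; 0.0773 with an estimated correlation; 1 when adjusted over the list alone). Mean hepatocyte marker levels per array differed by -0.26 (exact permutation p = 0.0303, adjusted p = 0.162).

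With the replicate number as a block within the paired 6-month arrays, Acot1, an acyl-CoA thioesterase and PPAR-alpha target, was called as well. Its difference between fish and olive oil was 3.46 ± 0.216 (adjusted p = 1.77e-06), against an SE of 0.978 and an adjusted p of 0.614 without the block. Acot1 signal was 221 ± 193 with olive, 326 ± 322 with sunflower and 1823 ± 1530 with fish oil at 6 months, and 109 ± 35.8, 155 ± 48.2 and 2480 ± 446 at 24 months (SD, n = 3). The second young fish oil liver held 53.5 against 2728 and 2688 in the other two. In the paired fit Hdc had an adjusted p of 0.00236.

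**Figure D4:**
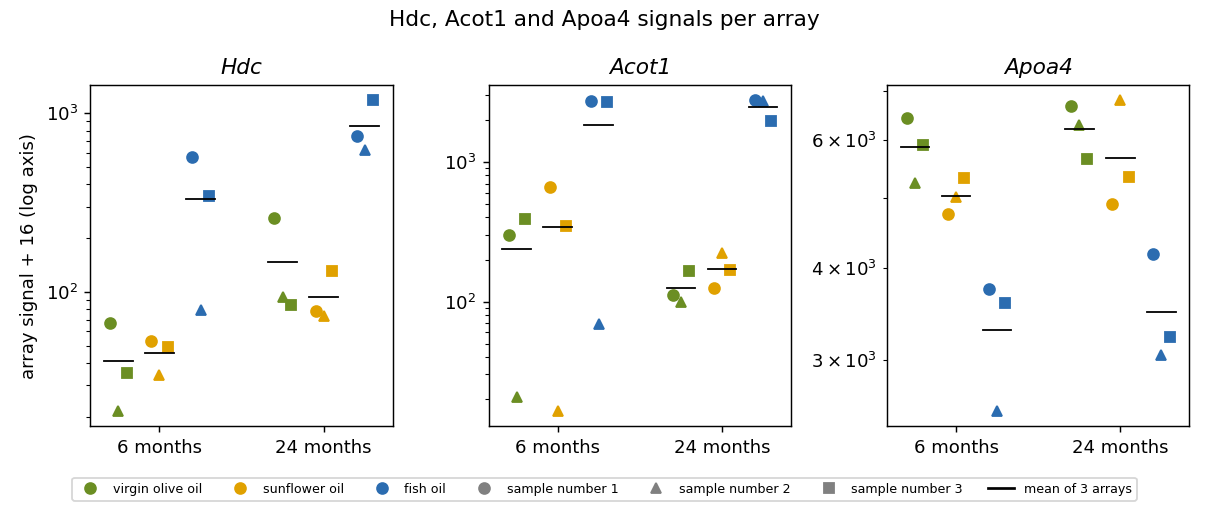
Signal plus 16 of Hdc, Acot1 and Apoa4 on each array (log axes), by age, oil (colour) and sample number (marker shape), with lines at the mean of each group of 3. Apoa4 means with fish oil, 3279 and 3465, lie below those with olive oil, 5845 and 6192.

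Against sunflower oil, averaged over ages, no gene passed, and Hdc, Tpd52l1 and Apoa4 were again among the 5 smallest p-values. Both comparisons use the same fish oil arrays. Hdc stood at 2.83 ± 0.42 (adjusted p = 0.0613), Tpd52l1 at 1.23 (0.138), the potassium channel Kcnk1 at -0.65, Apoa4 at -0.67 (0.22) and Clic2 at 1.11. Fatty acid synthesis (-0.49, camera adjusted p = 0.000345; 1 rose and 3 fell when adjusted over the list alone) and cholesterol synthesis genes (-0.33, adjusted p = 8.05e-05, 19 of 19 members negative) were lower, with adjusted p = 0.385 and 0.402 with an estimated correlation. PPAR-alpha targets (0.23, adjusted p = 0.000762) and antigen presentation genes (0.60, adjusted p = 1.06e-08; 2 when adjusted over the list alone) were higher, with adjusted p = 0.488 and 0.275 with an estimated correlation. Without the third fish oil liver at 24 months the antigen presentation median was 0.36 (adjusted p = 2.29e-05). Limma called 0 genes, with 961 at an unadjusted p under 0.05, and an ordinary linear model called 0. With a replicate block within the paired 6-month arrays 3 passed, Acot1 (3.13, adjusted p = 7.08e-06), Hdc (0.00143) and Rhof (1.26, 0.041). Without the second young fish oil liver 1 passed, and without the first old one 7.

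Between sunflower and olive oil no gene passed with all arrays fitted. C2cd3 (0.61), Cntfr (1.05), Atp4a (0.54), Kcnj14 (0.50) and Hbe1 (0.51) had the smallest p-values averaged over ages, with adjusted p from 0.663 to 0.828. Antigen presentation genes were lower with sunflower oil (-0.29, camera adjusted p = 0.000675; 18 of 19 members negative, 0 when adjusted over the list alone) and so were unfolded protein and heat shock genes (-0.14, adjusted p = 0.00746; 0 when adjusted over the list alone), both at adjusted p = 0.893 with an estimated correlation. The unfolded protein list did not pass without the number 2 arrays (0.051) or when quantile normalized again (0.115). Limma called 0 genes, with 604 at an unadjusted p under 0.05, and an ordinary linear model called 0. The antioxidant enzyme Nqo1 stood at 1.12 on average (adjusted p = 0.863) and at 1.77 at 24 months (adjusted p = 1), where its signal was 310 ± 32.7 with sunflower and 79.6 ± 3.94 with olive oil (SD, n = 3). With only the arrays of the groups compared, Nqo1 passed at 24 months (adjusted p = 0.0328) and Tifa averaged over ages (-1.01, adjusted p = 0.027). Without the third olive oil liver at 24 months Clic2 (-1.65) and Prlr (2.60) passed at that age (adjusted p = 0.0271 for both).

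At 6 months alone, the cholesterol synthesis and PPAR-alpha lists differed between fish oil and both other oils, with the preset correlation only. Both comparisons share the young fish oil arrays. Cholesterol synthesis genes were lower with fish oil than with olive oil (-0.50, camera adjusted p = 6.68e-06) and than with sunflower oil (-0.51, adjusted p = 0.000137), with every one of the 19 members negative in both, at adjusted p = 0.773 and 0.921 with an estimated correlation. Fatty acid synthesis genes were lower than with olive oil (-0.84, adjusted p = 0.000334; 0.773 with an estimated correlation), and PPAR-alpha targets were higher in both comparisons (0.23, adjusted p = 0.0042, and 0.28, adjusted p = 0.000845; 0.937 and 0.921 with an estimated correlation). No member of these lists passed when adjusted over the list alone. Without the number 2 arrays the cholesterol medians were -0.41 (adjusted p = 3.01e-05) and -0.35 (adjusted p = 0.00175), that of fatty acid synthesis against olive oil was -0.69 (adjusted p = 3.01e-05), and those of PPAR-alpha targets were 0.21 (adjusted p = 2.13e-05) and 0.23 (adjusted p = 0.000414). Apoa4 (-0.85), Fsd2 (-0.76), Cavin2 (-0.73), Hdc (2.75) and Resp18 (1.21) led fish against olive oil (adjusted p = 0.924). Adra2c (0.76), Gng10 (-0.65), Cyfip2 (-0.94), Slc6a17 (-0.73) and Kifc3 (-0.93) led fish against sunflower oil (0.926), and Fsd2 (-0.79), Atp4a (0.78), Eif4ebp3 (-1.66), Kcnk13 (0.93) and Chst3 (-0.61) led sunflower against olive oil (0.819). Limma called 0 genes in each, with 585, 573 and 550 at an unadjusted p under 0.05, and an ordinary linear model called 0. With the paired replicate block Acot1 passed against olive oil (2.58, adjusted p = 0.00803) and against sunflower oil (2.36, adjusted p = 0.0227), and without the second young fish oil liver 2 genes passed in each.

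Genes of lipid synthesis also differed between sample numbers at 6 months, within every oil. The desaturase Scd had mean signals of 13.5, 7696 and 11.43 in numbers 1, 2 and 3 (adjusted p = 2.89e-06), Fasn 68.2, 1718 and 64.3 (adjusted p = 5.13e-05) and the hormone Fgf21 331.5, 35.6 and 149 (adjusted p = 0.000374). The clock gene Per3 had 18.3, 40.5 and 2.37 (adjusted p = 0.023), and Pck1 did not differ (adjusted p = 0.996). Limma's F test of the number beside the oil called 181 genes at 6 months and 0 at 24 months, where 1012 had an unadjusted p under 0.05. What the numbers stand for is not given in the sources used here.

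**Figure D5:**
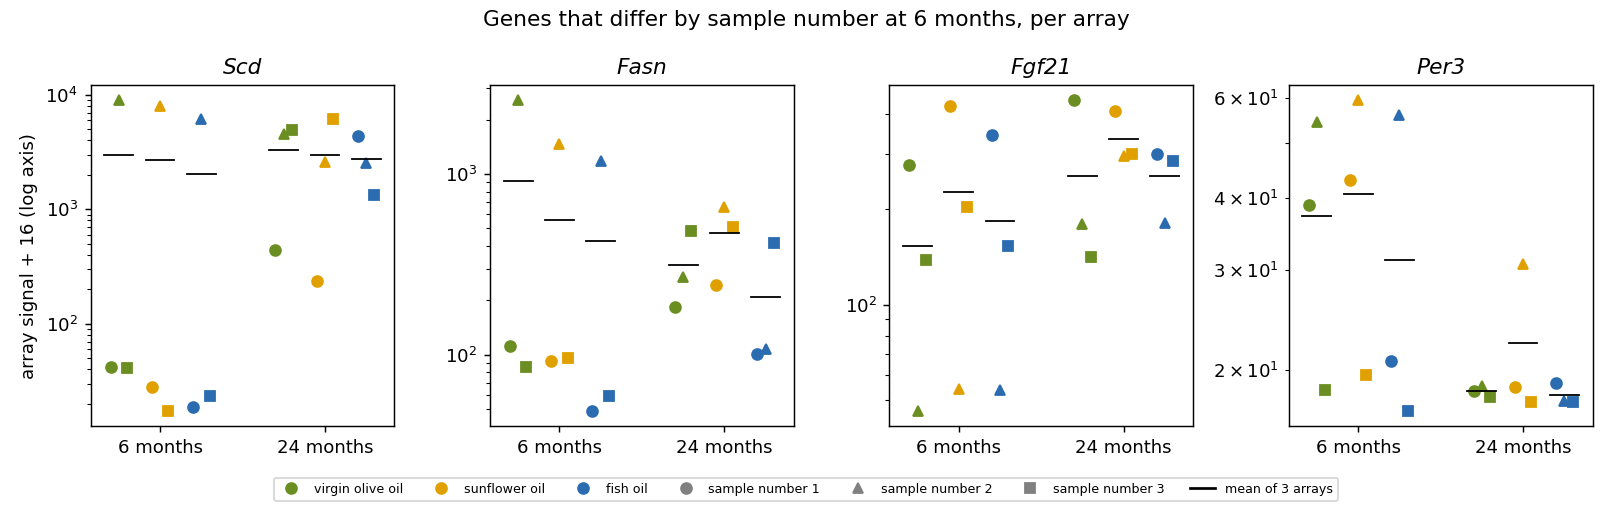
Signal of Scd, Fasn, Fgf21 and Per3 on each array by age, oil and sample number. At 6 months mean Scd signal was 7696 in number 2 and 13.5 and 11.43 in numbers 1 and 3.

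At 24 months the cell cycle list was higher with fish oil than with both other oils. Cell cycle genes were higher than with olive oil (0.38, camera adjusted p = 1.74e-09; 5 when adjusted over the list alone) and than with sunflower oil (0.42, adjusted p = 3.33e-11; 10 when adjusted over the list alone), and both calls held with an estimated correlation (adjusted p = 0.0118 and 0.00647). The third fish oil liver lay 0.37 above the other two in this list. Without it the medians were 0.34 (adjusted p = 2.72e-07) and 0.31 (adjusted p = 1.28e-08), and both calls held with an estimated correlation (adjusted p = 0.00293 and 0.00152). Antigen presentation genes were higher than with sunflower oil by 1.13 (adjusted p = 9.9e-17; 0.0891 with an estimated correlation; 16 of 19 when adjusted over the list alone), or 0.62 without the third fish oil liver (adjusted p = 5.85e-13), while sunflower oil lay below olive oil by a median of -0.53 (adjusted p = 1.17e-07; 0.522 with an estimated correlation; 1 when adjusted over the list alone). Against olive oil their median was 0.58 (1.81e-05; 0.379 with an estimated correlation; 0 when adjusted over the list alone), and 0.14 without the third fish oil liver (adjusted p = 0.19). T and NK cell markers were higher than with both oils (0.65, adjusted p = 2.14e-06, and 0.56, adjusted p = 1.91e-08; 0.194 and 0.0891 with an estimated correlation; 7 and 8 when adjusted over the list alone). The third fish oil liver lay 0.65 above the other two in this list, and without it the medians were 0.44 (adjusted p = 0.000759) and 0.40 (adjusted p = 3.78e-06). Oxidative phosphorylation genes were lower than with both (-0.32, adjusted p = 1.34e-21, and -0.27, adjusted p = 2.47e-15; 0.203 and 0.19 with an estimated correlation; 0 and 0 when adjusted over the list alone). Against olive oil this median was -0.20 when quantile normalized again (adjusted p = 2.2e-10). Mean hepatocyte marker levels (log2) were also lower on the old fish oil arrays, at 11.9 to 12.19. They were 12.21 to 12.42 with olive and 12.25 to 12.38 with sunflower oil. Whether the oxidative phosphorylation genes fell beyond these markers was not tested.

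With all arrays fitted no single gene passed at 24 months. The smallest p-values were those of Mcm5 (1.08, adjusted p = 0.0998), Tpd52l1 (1.77), Nceh1 (1.5), the chemokine receptor Cxcr3 (0.78) and Dock10 (1.09) for fish against olive oil. Dusp2 (1.32), Laptm5 (1.54, both adjusted p = 0.0502), Tpd52l1 (1.80), Cd7 (0.84) and Spn (1.98) led fish against sunflower oil, and Bdh2 (1.14), Tcof1 (-1.06), Nqo1, Cldn3 (-1.39) and Ptk7 (1.32) led sunflower against olive oil (adjusted p = 1). Limma called 0 genes in each, with 1135, 1310 and 568 at an unadjusted p under 0.05, and an ordinary linear model called 0. Counts of calls depended on single arrays. Without the first fish oil liver 53 genes passed against olive oil and 137 against sunflower oil, without the first sunflower oil liver 12 passed in the latter, and without the third olive oil liver 2 passed for sunflower against olive oil. With the replicate block within the paired young arrays Acot1 passed against olive oil (4.34, adjusted p = 9.09e-06) and sunflower oil (3.89, adjusted p = 3.99e-05), where Hdc and Dusp2 passed as well.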

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

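Tests of feeding state, hour of killing, a lower share of hepatocytes, compression of bright probe sets and 1 outlying array were chosen only after the result was seen. In 29 cases the age effect of a gene list differed between 2 oils by camera's test of the difference (groups of 3 arrays were not tested for outlying samples). For single genes limma called 0 for each difference between pairs of oils (787, 971 and 544 at an unadjusted p under 0.05).

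Of the lists that differed between fish and olive oil with the preset correlation, the median difference was 0.90 for antigen presentation, 0.78 for monocyte and granulocyte, 0.64 for T and NK cell, 0.50 for cell cycle, 0.39 for interferon, 0.39 for extracellular matrix, 0.36 for macrophage and 0.21 for acute phase genes, 0.61 for cholesterol synthesis genes, and -0.32 for oxidative phosphorylation, -0.43 for male-biased and -0.14 for xenobiotic genes. With an estimated correlation no call held, with adjusted p = 0.0738 for cell cycle and from 0.401 to 0.525 for the others. Without the third fish oil liver at 24 months the interferon (0.05, adjusted p = 0.583), macrophage (0.30, adjusted p = 0.304), monocyte (0.11, adjusted p = 0.317), acute phase (0.10, adjusted p = 0.106) and xenobiotic lists (0.005, adjusted p = 0.867) did not pass. Antigen presentation then stood at 0.32, T and NK cell genes at 0.36 and cell cycle genes at 0.37 (adjusted p = 0.000171; 0.0219 with an estimated correlation), and the male-biased list turned to 0.02 (adjusted p = 0.867).

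Against sunflower oil the rise with fish oil was larger by 1.22 for antigen presentation, 1.17 for interferon, 1.08 for monocyte and granulocyte, 0.68 for macrophage, 0.65 for stellate cell, 0.62 for T and NK cell, 0.47 for cell cycle, 0.35 for extracellular matrix, 0.25 for unfolded protein and 0.16 for acute phase genes. The difference was -0.35 for oxidative phosphorylation, -0.20 for mitochondrial biogenesis, -0.19 for xenobiotic and -0.15 for hepatocyte genes. With an estimated correlation the cell cycle call held (adjusted p = 0.032) and the others did not (0.16 to 0.421). Without the third fish oil liver at 24 months the differences were 0.74 for antigen presentation, 0.57 for interferon, 0.40 for monocyte and granulocyte and 0.48 for macrophage genes, and the xenobiotic (-0.008, adjusted p = 0.574) and unfolded protein lists (0.18, adjusted p = 0.293) did not pass. Sunflower minus olive oil gave -0.53 for antigen presentation, -0.45 for interferon and -0.24 for unfolded protein genes, all at adjusted p = 0.852 with an estimated correlation.

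The third fish oil liver at 24 months stood apart, with 537 genes over 2-fold from both other arrays of its group. Scaling was argued against, as quantile normalization left 554 such genes. A female sample was argued against, as 4 of 4 sex-linked genes lay within the range of the other 17 arrays. This rests on the Y-linked Eif2s3y (305, range 269 to 476.2) and Uty (165.7, range 100.1 to 209.4). Sry was low on the other arrays too (0.3 to 20.3), so it could not tell the sexes apart. Xist was also low there (0.2 to 10.9), and whether its probe set detects the transcript was not tested. A lower share of hepatocytes as the whole cause was argued against, as medians of the other cell types lay 1.92 apart, from 1.6 for monocyte and granulocyte to -0.33 for endothelial genes. A change in the cell types that rose, such as an inflamed liver, stays open and may underlie part of the fish oil differences.

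Number 2 livers at 6 months stood apart from numbers 1 and 3 in each oil. Genes over 2-fold from both other arrays of the group numbered 197 to 259 for number 2 and 58 to 139 for numbers 1 and 3. Limma's F test called 181 genes that differed among the 3 numbers, which also counts differences between numbers 1 and 3. Scaling was argued against, as 172 genes differed by number after quantile normalization. Number 2 then had 196 to 255 genes over 2-fold from both other arrays. Feeding state is a candidate explanation, as 6 of 6 medians of the lipogenic list (higher) and the PPAR-alpha list (lower) went its way. Both lists were read on the same livers, so the 6 medians are not independent of each other. Pck1 did not differ by number. The hour of killing is another, as the clock list's mean absolute difference was at percentile 100 of random lists. On this measure cholesterol synthesis genes also stood at 100, gluconeogenesis genes at 99.64 and interferon genes at 99.54. A high percentile was thus not particular to clock genes, and 2 of 18 clock genes were called in the F test of the number. Feeding state and hour of killing both stay open, and neither feeding nor hour per animal is given in the sources used here.

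Oxidative phosphorylation genes were lower at 24 months, 56 of 57 negative, with a median of -0.29, and of -0.193 when quantile normalized again. Camera's call of this list was lost with an estimated correlation. Mean hepatocyte marker levels per array differed by -0.19 with age (exact permutation p = 0.0156, adjusted p = 0.125), and a shift shared with them was not tested. Compression of bright probe sets as the whole cause was argued against, as the median lay at -0.104 relative to the lower bound of lists matched on signal. Those lists ran from -0.186 to -0.056, so part of the fall was common to equally bright genes. Their members were drawn at random and so lacked the correlation between genes of 1 pathway. Dependence on 1 outlying array was argued against, as the median was -0.28 without the third fish oil liver at 24 months. A lower level with age beyond that part may remain, as a hypothesis found and tested on the same data.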

How the results depend on the processing

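The pseudocounts, the block within 6 months, the fit without number 2 at 6 months the list tests without the third fish oil liver at 24 months and the splits with that block were chosen after the data were seen; causes of the moves below were not tested. Ageing averaged over oils gave 455 genes with a pseudocount of 1 and stayed within 1.5 times of 734 in the other alternatives (589 to 1026), though without number 2 only 415 of the 734 were among the 628 called (all 734 kept their sign); leaving out each array gave 489 to 968. Counts with all probe sets are, throughout, of probe sets and not of genes. Ageing with olive oil gave 35 with all probe sets. It gave 0 genes with an ordinary linear model, 8 with a pseudocount of 1 and 39 with the block within 6 months. Without number 2 it gave 1 and with only the groups compared 8 (3 to 25 leaving out each array). Ageing with sunflower oil gave 17 without the dimmest genes, 9 with all probe sets, 5 with the replicate block, 17 with the block within 6 months and 1 with only the groups compared (0 to 13). Ageing with fish oil gave 113 with all probe sets, 101 quantile normalized again, 23 with an ordinary linear model, 3 with a pseudocount of 1, 113 without number 2 and 3 with only the groups compared (7 to 562).

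Fish against olive oil averaged over ages gave 1 gene with trend and robust, with the mean of probe sets, quantile normalized again, with the replicate block and with a pseudocount of 64, and 0 with all probe sets, an ordinary linear model, a pseudocount of 1 and only the groups compared (0 to 2). Fish against sunflower oil gave 1 without the dimmest genes, with the replicate block and with only the groups compared, 3 with the block within 6 months and 2 without number 2 (0 to 7). Sunflower against olive oil gave 1 with only the groups compared (0 to 0), and 1 at 24 months (0 to 2; at 6 months 0 to 0). At 6 months fish oil gave 1 gene against olive oil with the block within 6 months and without number 2 (0 to 2), and 1 against sunflower oil with the block within 6 months (0 to 2). At 24 months it gave 1 against olive oil with the block within 6 months, without number 2 and with only the groups compared (0 to 53). Against sunflower oil it gave 4 without the dimmest genes and without number 2, 5 with trend and robust and with the replicate block, 2 with a pseudocount of 64, 3 with the block within 6 months and 1 with only the groups compared (0 to 137). The interaction gave 0 to 5. The blocks changed no other count by over 1.5 times.

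Of 512 list tests 159 passed. With an estimated correlation 154 calls were lost (145 lost and 6 turned when the third fish oil liver was also left out), quantile normalized again 34, without the third fish oil liver 30, without number 2 23, without the dimmest genes 4 and with the block within 6 months 1. Without number 2, cholesterol synthesis turned to 0.042 in ageing averaged over oils and 0.10 with sunflower oil, and PPAR-alpha targets to -0.09 and -0.078. Without the third fish oil liver, male-biased genes turned to 0.05 against olive oil averaged over ages, 0.077 at 24 months and 0.019 in the difference of age effects. Xenobiotic genes turned to 0.053 against olive oil and 0.11 against sunflower oil at 24 months, and antigen presentation against olive oil averaged over ages kept a positive median of 0.061 while camera's direction turned. Quantile normalized again, acute phase genes against olive oil averaged over ages stood at 0.003.

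For ageing averaged over oils, 1 of 100 splits of the arrays, the real one, gave as many genes (734; highest other 1), a share under 0.05. These splits were a draw from all possible ones and ignored the pairing at 6 months. They mixed old and young livers, which widens the spread within groups and lowers the other counts. A batch or cohort that went with age was not tested by them. For fish against olive oil averaged over ages chance was not excluded (5 of 100 splits; 2 genes, highest other 3), in splits that ignore the pairing at 6 months. With the block within 6 months, where Acot1, Hdc and Apoa4 passed, 1 of 80 splits that part every pair, the real one, gave as many (3 genes, highest other 1). Fish against sunflower oil gave the same with that block (1 of 80, with 3 genes and 1 as the highest other). The splits between oils mixed livers of the oils compared. For genes that differ this widens the spread within groups and lowers the other counts. Where the real count was 0, every split reached it and the splits decided nothing: fish against sunflower oil without the block (100 of 100; highest other 4), sunflower against olive oil (100 of 100; 2, and 80 of 80; 2 with the block) and the interaction (100 of 100; 49). A split with 49 genes points to a structure of the samples, and what it grouped was not tested. The 10 splits of 3 against 3 were too few for a share under 0.05. The real count and the highest other were 20 and 0, 0 and 0, and 243 and 0 for ageing with olive, sunflower and fish oil. They were 0 and 2, 0 and 0, and 0 and 1 at 6 months and 0 and 1, 0 and 1, and 0 and 0 at 24 months for fish against olive, fish against sunflower and sunflower against olive oil. Groups of 3 arrays and dim probe sets limit the precision.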

Other observations

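The third old fish oil liver, given as values only, held Obp3 at 111.3 against 6445 and 6067.5, Cyp3a2 at 118.7 against 6542.8 and 5451.1 and Hao2 at 26.7 against 1066.3 and 914.5 in the other two. Probe sets with no or several gene names numbered 10216, of which 176 passed for ageing averaged over oils, 139 higher and 37 lower.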
